A study of Mus musculus with 2 samples.

How the data were processed

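ATAC-seq was done on liver of mouse embryos at embryonic day 12.5, per the labels with Nextera tagmentation and a fragment size range of 200 to 750 bp. The 2 libraries are biological replicates from separate pools of 120 and 88 embryos and form 1 group. All values come from the deposited peak lists on the mm10 assembly. For each library there was a relaxed list, ranked by the irreproducible discovery rate (IDR, a measure of how consistently a peak ranks in 2 lists), an IDR-thresholded list and a pseudoreplicated list, and for the series as a whole a ranked, an IDR-thresholded, a conservative IDR-thresholded, a replicated and a pooled pseudoreplicated list. Per the deposited descriptions, the authors derived each ranked list from filtered alignments of the library, or of both libraries, and every other list from these together with 1 further reference file, whose content is not given in the sources used here. The peak caller, the aligner and their settings are not given in the sources used here either.

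The signal of a peak is the deposited signal value that the authors' peak calling wrote, and how it was scaled is not stated. The score is the deposited peak score, a whole number between 540 and 1000 in the authors' conservative list. The −log10 p of a peak is that of the authors' peak caller as deposited, and the whole-series ranked list also holds the −log10 p of the matched peak in each of the paired lists, without saying which library each is. In that list 6 further columns (positions and summits of the matched peaks in both lists) were not used, nor was a second ranked list of the whole series that pairs pseudoreplicates. Read counts were not used here, so the depth per library is unknown; the number of peaks, 50026 and 43310 in the thresholded lists, stands in for it, and no counting interval can be given for a peak.

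Overlapping or identical sub-peaks of a list were merged into regions, each represented by its strongest summit, on chromosomes 1 to 19, X and Y. The annotation was GENCODE M21 on the same assembly, with 21853 protein-coding genes and 54361 transcription start sites. A summit within 1000 bp of a start site was a promoter summit, and the others were classed as 5′ untranslated region, coding exon, 3′ untranslated region, intron or intergenic, in that order. A distal region was assigned to the gene with the nearest start site within 50000 bp and to any gene whose body held its summit.

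The comparisons, their tests, the gene lists, the loci, the consensus sequences and the rule for named genes were fixed before the data were examined. The overlap of the libraries' regions (at least 1 bp) and the distribution over the annotation were set beside 100 circular shifts of the regions along each chromosome. Each of 19 gene lists was compared with all other protein-coding genes by Fisher's exact test (two-sided) on promoter peaks, and by a permutation test (two-sided, 100000 random lists drawn within 10 classes of domain length) on the mean number of distal peaks. The Benjamini-Hochberg adjustment was over the 19 lists, with a threshold of 0.05. Of the planned members, 2 were not found as protein-coding genes under the symbol given (Ahsp and Clec7a). The lists were erythroid, heme synthesis and iron, megakaryocyte, stem and progenitor, myeloid and macrophage, lymphoid, hepatoblast secreted proteins, hepatic transcription factors, adult hepatocyte metabolism, cholangiocyte, endothelial, stellate with mesenchymal and mesothelial, cell cycle, ribosomal protein, neuron, muscle, other endoderm, germ line and pluripotency, and olfactory receptor. For 12 loci, regions were counted from 50 kb before the first to 50 kb after the last start site. Windows of 100 kb were ranked by their number of regions.

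For 24 consensus sequences, the share of distal windows (75 bp either side of the summit, both strands) with the sequence was divided by that of windows 2000 bp to the right that touched no peak of the relaxed list. The log ratio was ranked among up to 50 shuffled versions of the sequence (8 distinct ones for SP and 34 for RUNX), two-sided by its distance from their median, and adjusted over the 24. The smallest p that 50 versions allow is 0.0196. The regions and genes are not replicates, so no p measures variation between animals, and the libraries' own lists give the spread. No test between groups exists with 1 group.

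Genes were named by rule. For each list, they were up to 3 members with the strongest promoter peak, up to 3 with the most distal peaks and up to 3 without a promoter peak in alphabetical order. The genes nearest to the 10 strongest promoter and the 10 strongest distal peaks were also named, as were up to 3 genes in each of the 10 densest windows and the genes of the loci. Of those without a promoter peak and those in windows some were left out.

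The test procedures were tested on simulated data with known answers. Of 120 simulated lists with a raised share of open promoters 118 were called, and of 260 unchanged lists 5. For distal peaks the numbers were 108 of 120 and 3 of 260. In the simulation all unchanged genes had the same 50% share of open promoters, whatever their CpG content. Distal counts followed the class of domain length alone, without single genes of very many peaks. The rates therefore hold for that simpler setting and may differ in the real data. All 12 planted consensus sequences reached the smallest p, as did 3 of 12 that were not planted. These 3, GATA, AP-1 and NEUROD, can each lie inside a planted sequence, and so can a further 6 that were not called.

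Alternatives were the other 3 peak lists of the series, each library left out, the stronger 0.5 of the peaks by signal, other overlap criteria (50% of each region, summits within 100 bp, lists of equal size, pseudoreplicated lists), promoter windows of 500 and 2500 bp, the outermost start sites alone, random lists matched on promoter CpG content, assignment within 100 kb, no matching on domain length, every sub-peak counted, motif windows of 50 and 150 bp either side, and background windows matched on GC content. After the data were seen, 3 more were added: up to 1000 shuffled versions per consensus, genes over 1 Mb left out, and regions within 100 bp of an annotated tRNA gene left out. Sequence copies were sought by shared 31-mers. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.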

Results

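Open chromatin was mapped by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in liver of mouse embryos of strain B6NCrl at embryonic day 12.5. At this stage the liver is the main site of blood formation, and its hepatoblasts have not yet matured into hepatocytes. The series held 2 libraries of 1 group. Replicate 1 came from a pool of 120 embryos and replicate 2 from a pool of 88, both of mixed sex. No other stage, tissue or treatment was in the series, so each comparison below sets sites, genes or sequences against others in the same tissue, and the libraries' own lists give the spread. Read depth is unknown, because the values used here are peak lists without read counts, and the sizes of the lists stand in for it. The authors' own list held 50026 peaks for replicate 1 and 43310 for replicate 2. Their conservative list from both libraries held 58571 peaks, which merged into 26844 regions covering 20.6 Mb of the mm10 assembly, and unless stated otherwise values refer to these regions. Their median width was 733 bp, and 665 lay on chromosome X and 11 on chromosome Y. Signal is the authors' signal value of a peak, whose scale is not given in the sources used here, and the median over regions was 9.24.

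The accessible sites of the pools were largely the same, and the strongest were shared almost without exception. Of the 23954 regions of replicate 1, 79.4% were overlapped in replicate 2, and of the 20174 regions of replicate 2, 94.4% were overlapped in replicate 1. Promoter regions were shared more often than distal ones, at 91.1% against 69.9% in replicate 1 and at 97.54% against 91.3% in replicate 2. Shared regions had a median signal of 12.2 in replicate 1 and unshared ones 5.95, and in replicate 2 the medians were 10.4 and 5.78. In the strongest decile of signal of replicate 1, 99.96% of regions were overlapped and in the weakest 39.5%, as the plot of overlap by decile shows; the shares for replicate 2 were 100% and 81.3%. When the regions of replicate 1 were moved along their chromosomes 100 times, 1.20% of them overlapped replicate 2's list on average, and at most 1.47%. The moved regions overlapped 1.41% of replicate 2's unmoved regions on average, and at most 1.71%. Against the other library's relaxed list, the shares were 97.2% and 99.7%, which left 665 regions of replicate 1 and 56 of replicate 2 without a partner. The −log10 p values of 103201 matched peaks had a Spearman correlation of 0.805 across peaks, which are not independent replicates.

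**Figure D1:**
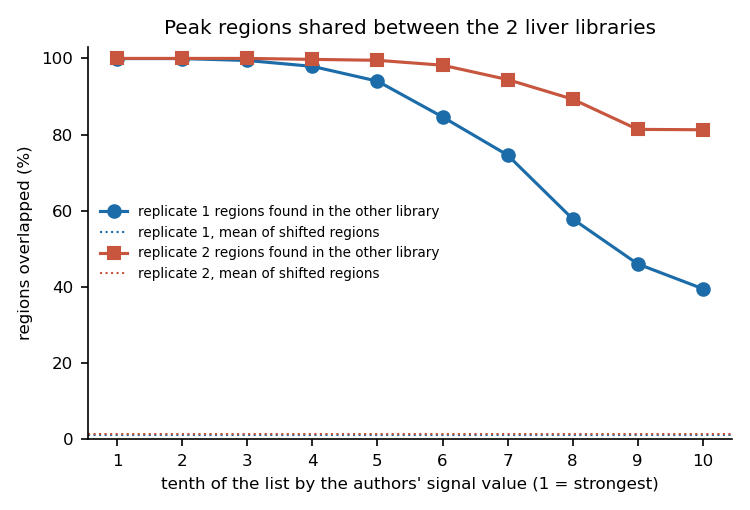
Share of each library's merged peak regions overlapped by at least 1 bp in the other library's list (percent, vertical axis), by decile of the authors' signal value within the list (horizontal axis), 1 line per library. The weakest decile of replicate 1 stood at 39.5% and that of replicate 2 at 81.3%.

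Promoters of protein-coding genes were the largest class of accessible site in the conservative list and had the highest median signal. Of the 26844 regions, 11197 (41.7%) had their summit within 1 kb of a transcription start site, with 47.2% ± 3.503 (SD, n = 2) in the libraries' own lists and 2.57% after moving the regions along their chromosomes, a 16.2-fold difference. Introns held 8327 summits (31.02%) and intergenic sequence 6698 (24.95%), against 36.0% and 59.0% after moving. The introns' share was 28.04% ± 2.09 (SD, n = 2) and the intergenic share 22.6% ± 1.22 (SD, n = 2) in the libraries' own lists. Coding exons (301), 3′ untranslated regions (298) and 5′ untranslated regions (23) held the remainder. Promoter regions had a median signal of 12.1 and a median width of 1001 bp, intronic regions a median signal of 7.54 and a width of 545 bp, and intergenic regions 7.68 and 591 bp. A promoter peak lay at 11060 of 21853 protein-coding genes (50.6%), at 48.6% in replicate 1 and 46.6% in replicate 2. The other 15647 regions are called distal here, and 12089 of them lay within 50 kb of a start site. Regions further away but inside a gene body were also assigned to that gene. No group was compared with another, so these shares carry no test. The promoter share was 26.7% in the authors' replicated list and 26.2% in their pooled pseudoreplicated list, both of which hold more weak peaks, and there introns (38.6% and 39.03%) and intergenic sequence (31.1% and 31.2%) each held more summits than promoters.

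Genes of red cells and of dividing cells had open promoters. A promoter peak lay at 28 of 31 erythroid genes (90.3% in the combined list and in each library), at all 20 genes of heme synthesis and iron uptake, at all 27 cell cycle genes and at all 36 ribosomal protein genes. Trim10 (chromosome 17, 36869574 to 36877833) had a promoter signal of 22.03, at percentile 97.4 of genes with a promoter peak, and Epb42, which encodes a protein of the red cell membrane skeleton, had 21.4. Nfe2, a transcription factor of red cells and platelets, had 16.3. The adult globin genes Hbb-bs, Hbb-bt, Hba-a2 and Hba-a1 had promoter signals of 10.8, 8.48, 8.42 and 5.89, whereas the embryonic globin genes Hba-x, Hbb-bh1 and Hbb-y were the 3 erythroid genes without a promoter peak, in the combined list and in both libraries' lists. In the replicated and the pooled pseudoreplicated lists, which hold weaker peaks, all 31 erythroid genes had one, these 3 included, and among the stronger peaks by signal the share was 58.1%. Among heme and iron genes, Snx3 had a signal of 19.1, the mitochondrial iron importer Slc25a37 17.4 and Cpox, an enzyme of heme synthesis, 17.2. The mitotic genes Ccnb2, Bub1 and Ccna2 had 21.7, 19.3 and 18.7, and the ribosomal protein genes Rps5, Rpl27 and Rpl5 had 17.2, 17.1 and 16.3. By Fisher's exact test (two-sided, against all other protein-coding genes, Benjamini-Hochberg over 19 lists) the adjusted p was 1.14e-05 for erythroid, 6.16e-06 for heme, 9.78e-08 for cell cycle and 2.94e-10 for ribosomal protein genes. The rate among other genes was close to 50.6% for each list; random lists matched on promoter CpG content gave 33.9% for the erythroid list, 69.1% for heme, 78.1% for cell cycle and 81.7% for ribosomal protein genes.

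Genes of mature liver and of tissues outside the liver had few open promoters in the conservative list. A promoter peak lay at 6 of 35 genes of adult hepatocyte metabolism (17.1%), among them Glul, which makes glutamine, with a signal of 16.5, Asl of the urea cycle with 10.2 and Pah, which hydroxylates phenylalanine, with 6.64. Of 31 muscle genes 2 had one (6.45%; Mylpf 10.4 and Ryr2 6.01), of 22 germ line and pluripotency genes 1 (4.55%; Dazl 16.9), of 23 genes of other endoderm 2 (8.70%; Nkx6-1 14.3 and Cpa1 6.30) and of 27 neuronal genes 5 (18.5%, with Syp at 10.9, Isl1 at 10.1 and Elavl4 at 7.12). Among 1134 olfactory receptor genes, 3 had one (0.265%). These were Olfr68 (16.4), Olfr575 (15.8) and Olfr646 (6.76), all on chromosome 7, where Olfr68 lies inside the β-globin region examined below. Olfr646 and Cpa1 had no promoter peak in either library's own list, and Ryr2 and Elavl4 none in that of replicate 1. Without replicate 1 the adult hepatocyte share was 8.57%, without replicate 2 the muscle share was 3.23%, and the neuronal share was 11.1% in each library. Over 10 alternatives the germ line share ranged from 4.55% to 13.6% and the olfactory receptor share from 0.176% to 1.41%, and both calls held in all 10. Adjusted p (Fisher's exact test, same family of 19 lists) was 0.000101 for adult hepatocyte, 8.73e-07 for muscle, 1.14e-05 for germ line, 6.23e-05 for other endoderm and 0.00109 for neuronal genes, and for olfactory receptors it was below the smallest number that the software holds. Matched on promoter CpG content, the adult hepatocyte list no longer differed (13.9% expected, adjusted p = 0.679 by permutation) and its direction turned (range of adjusted p 4.11e-06 to 0.679 over 10 alternatives). The neuronal call ended in the replicated (44.4%) and the pooled pseudoreplicated (48.1%) lists and that for other endoderm in the pooled pseudoreplicated list (39.1%), and the adult hepatocyte share was 40% in the replicated list, where its call held, as did that for muscle genes (16.1%).

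Markers of the liver's minority cells also had few open promoters in the conservative list. Of 28 myeloid and macrophage genes 2 had one, Fcgr3 (7.37), an immunoglobulin receptor, and Spi1 (6.68), the gene of the factor PU.1. Of 25 lymphoid genes 4 had one (16%), of which Ebf1 (12.8; 8.45 in replicate 2), Pax5 (12.1) and Lck (10.8) were strongest. Ets1 (20.6), Plvap (10.4) and Egfl7 (4.47) were the 3 of 25 endothelial genes (12%), and Alcam (11.5), Gata4 (6.41) and Lhx2 (6.23) led the 4 of 29 stellate, mesenchymal and mesothelial genes (13.8%). Of 14 cholangiocyte genes 2 had one, Muc1 (3.74) and Bicc1 (3.56). Muc1 and Gata4 had no promoter peak in either library's own list, Bicc1 and Lhx2 none in that of replicate 2 and Egfl7 none in that of replicate 1. Without replicate 1 the stellate share was 6.897% and the cholangiocyte share 0%, and without replicate 2 the myeloid share was 10.7%, the cholangiocyte share 7.14% and the endothelial share 8%. Adjusted p (Fisher's exact test) was 4.78e-06 for myeloid, 0.000677 for lymphoid, 0.000117 for endothelial, 9.4e-05 for stellate and 0.00854 for cholangiocyte genes. Against lists matched on CpG content, the myeloid (adjusted p = 0.0767 by permutation; range 1.28e-06 to 0.0767 over 10 alternatives) and lymphoid (0.134; range 4.38e-06 to 0.134) calls ended. The endothelial and cholangiocyte calls ended in the replicated and the pooled pseudoreplicated lists, where the shares were 60% and 57.1% in each, and the stellate call ended in the replicated list (44.8%). The myeloid share was 28.6% in both lists, and its call held there. The lymphoid share was 28% in the pooled pseudoreplicated list, 8% with the outermost start sites alone and 4% with a promoter window of 500 bp, and its call held in each. With 500 bp the myeloid share was 3.57% and the cholangiocyte share 7.14%, and with 2500 bp the endothelial share was 20%.

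In the conservative list promoters of hepatoblast genes were open at some genes and weakly so. A promoter peak lay at 9 of 28 genes of secreted hepatoblast proteins (32.1%; adjusted p = 0.0696, Fisher's exact test), and the median signal of these promoters stood at percentile 2.84 of all genes with a promoter peak. Apob, which encodes the apolipoprotein of low-density lipoprotein, had 7.41, the thyroxine carrier Ttr 6.98 and fibrinogen gene Fgg 5.82, and Apob and Ttr had no promoter peak in either library's own list and Fgg none in that of replicate 1. Afp, Alb and Apoa1 had none in any of these lists. Hepatic transcription factors had a promoter peak at 11 of 22 genes (adjusted p = 1, Fisher's exact test), with Xbp1 at 16.6, Foxa3 at 13.1 and Tbx3 at 9.08. Of 22 megakaryocyte genes 9 had one (adjusted p = 0.447, Fisher's exact test), including Gp1ba (14.1; 16.2 in replicate 1 and 8.92 in replicate 2), Itga2b (8.98) and Rab27b (8.75), and of 23 stem and progenitor genes 11 (adjusted p = 0.884, Fisher's exact test), including Runx1 (13.1), Lmo2 (11.4) and Hlf (10.7). Against random lists matched on promoter CpG content none of these lists passed by permutation. Hepatoblast genes stood above the 17.2% expected (adjusted p = 0.053 by permutation) and megakaryocyte genes (40.9%) above 27.0% (0.102). Hepatic factors stood below 62.3% (0.194) and stem and progenitor genes below 65.9% (0.0767). In 4 of 10 alternatives each, the hepatoblast and megakaryocyte lists passed as lower than other genes by Fisher's exact test. These were each library's own list, a window of 500 bp and the stronger peaks. Hepatoblast genes stood at 14.3% without replicate 2 (adjusted p = 0.000279 by the exact test) and at 3.57% without replicate 1 (2.72e-06), with a range of 2.72e-06 to 1 over 10 alternatives. With 500 bp the hepatoblast share was 28.6% (0.042 by the exact test) and among the stronger peaks 0% (8.05e-06). The hepatoblast share was 71.4% in the replicated list, 67.9% in the pooled pseudoreplicated list and 53.6% with a promoter window of 2500 bp, none of which passed. Hepatic transcription factors stood at 77.3% in the replicated and the pooled pseudoreplicated lists, which did not pass, and at 9.09% among the stronger peaks, where they passed as lower (adjusted p = 0.00463 by the exact test). Megakaryocyte genes stood at 22.7% in each library (0.0198 and 0.0346 by the exact test; range 0.00102 to 1), at 22.7% with 500 bp and at 4.55% among the stronger peaks.

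**Figure D2:**
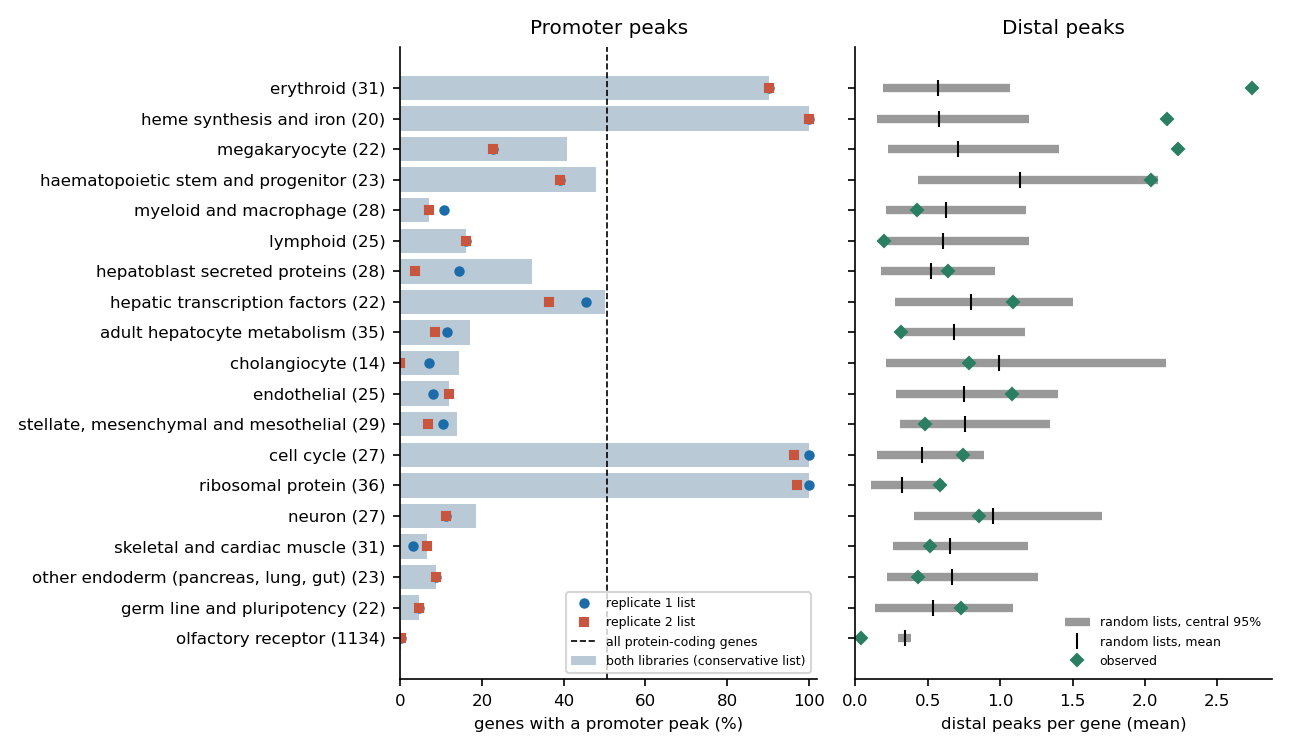
Left, share of each gene list's members with a promoter peak (percent), with bars for the conservative list, points for each library's own list and a dashed line for all protein-coding genes. Right, mean number of distal peaks per gene in the conservative list, with the mean and the central 95% of random lists matched on domain length; erythroid genes stood at 90.3% and 2.74 distal peaks per gene, and olfactory receptor genes at 0.265% and 0.0362.

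Distal accessible sites were more numerous around erythroid, heme and megakaryocyte genes than around matched genes. Erythroid genes had 2.74 distal peaks per gene against 0.568 in random lists matched on the length of the gene's domain, a 4.83-fold difference (5.15-fold in replicate 1 and 5.61-fold in replicate 2), and 25 of 31 had at least 1. Bpgm, which makes the red cell's 2,3-bisphosphoglycerate, had 9, and Ank1 and Epb41, of the membrane skeleton, had 8 each. Heme and iron genes had 2.15 against 0.577 (3.72-fold, with 4.43-fold and 4.89-fold in the libraries), led by Glrx5 with 6 and Snx3 with 5. Alad was tied with other members at 4. Megakaryocyte genes had 2.23 against 0.707 (3.15-fold; 3.49-fold and 3.57-fold), led by Zfpm1 with 12, the gene of a cofactor of GATA1, and by Fli1 and Rab27b with 6 each. Replicate 2's own list gave 4 for Bpgm and 5 for Epb41, and the lists of replicates 1 and 2 gave 2 and 1 for Alad and 4 and 2 for Fli1. Olfactory receptor genes had 0.0362 against 0.340, and Olfr1423 had the most, 6. By permutation (100000 random lists, two-sided, Benjamini-Hochberg over 19 lists) the adjusted p was 0.0168 for erythroid, 0.012 for heme, 0.0188 for megakaryocyte and 0.00038 for olfactory receptor genes, the last from the smallest p the permutations can give, 2e-05. These 4 lists passed in 10 of 10 alternatives, in which the mean number of distal peaks ranged from 0.968 to 5.23 for erythroid, 0.7 to 4.15 for heme and 0.773 to 4.27 for megakaryocyte genes.

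Other lists did not pass this test. Stem and progenitor genes had 2.04 distal peaks per gene against 1.14 (adjusted p = 0.198 by permutation), with 8 at Runx1 and 4 each at Angpt1 and Cd34 (2 each in replicate 2's list), and passed only when lists were not matched on domain length (0.0178; range 0.0178 to 0.448 over 10 alternatives). Hepatoblast genes had 0.643 against 0.520 (adjusted p = 0.660 by permutation), with 2 each at Afp (none in either library's own list), Dlk1 and F2, and hepatic transcription factors 1.09 against 0.799 (0.5998), with 4 at Rxra and 2 at Cebpa. In the lists of replicates 1 and 2 the hepatoblast mean was 0.286 and 0.214 and that of hepatic factors 0.682 and 0.455. Endothelial genes had 1.08 against 0.749 (adjusted p = 0.526 by permutation), with 3 each at Egfl7, Eng and Kdr; the libraries' own lists gave 0.72 and 0.44, and replicate 2 gave 1 for each of these genes. The cell cycle genes had 0.741 against 0.461 (0.372), with 5 at E2f2 and 4 each at Aurkb (2 in replicate 2's list) and Rrm2, and ribosomal protein genes 0.583 against 0.325 (0.198), with 0.417 and 0.306 in the lists of replicates 1 and 2. Lymphoid genes had 0.2 against 0.603 (adjusted p = 0.198 by permutation; 0.12 in replicate 2's list), adult hepatocyte genes 0.314 against 0.682 (0.198), with 4 at Hpd, and myeloid genes 0.429 against 0.627 (0.632), with 7 at Fcgr3 and 3 at Cx3cr1. In the 100 kb window of Fcgr3, 12 of 14 regions lay within 100 bp of a tRNA gene. Adjusted p was 0.869 for cholangiocyte genes (7 distal peaks at Aqp1), 0.5998 for stellate genes (5 at Reln, 3 in each library's list), 0.903 for neuronal genes (5 at Syt1), 0.731 for muscle genes (9 at Ryr2), 0.629 for other endoderm (4 at Sftpb) and 0.629 for germ line genes (5 at Tnp1), all by permutation. The ribosomal protein list passed by permutation in the replicated (adjusted p = 0.00703) and the pooled pseudoreplicated (0.0345) lists, with a range of 0.00703 to 1 over 10 alternatives.

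The globin clusters held many more accessible regions than stretches of their length hold on average. The region from 103763996 to 103903215 on chromosome 7, around the β-globin genes, held 14 regions (14 in replicate 1 and 13 in replicate 2), where a stretch of that length holds 1.37 on average. Upstream of Hbb-y, where the cluster's locus control region lies, summits stood at 103859300 (signal 14.2), 103861136 (8.87), 103865932 (14.1), 103870897 (11.3) and 103877294 (14.1). The region around the α-globin genes, chromosome 11 from 32226400 to 32346488, held 16 (15 and 13), against 1.18. Its strongest summits lay at 32256329 (22.7), 32251017 (21.5) and 32245802 (16.9), all in introns and near Nprl3, whose body is known to hold enhancers of the α-globin genes. Around Tal1 there were 9 (9 and 7), around Klf1 10 (10 and 8), around Gata1 6 (5 and 5) and around Kit 4 (3 and 4), against averages of 1.02, 0.985, 1.12 and 0.985. The β-globin count includes the promoter of the neighbour Olfr68 (16.4). The α-globin count includes those of Nprl3 (7.57) and Mpg (11.3), the latter named after its value was seen. The counts for Tal1, Klf1 and Gata1 also include promoters of neighbours, named after their values were seen. These are Pdzk1ip1 near Tal1, Farsa, Syce2, Gcdh, Dnase2a and Mast1 near Klf1, and Hdac6 near Gata1. A summit 15416 bp from the nearest start site of Gata1, at 7993487 on chromosome X, had a signal of 15.3.

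The albumin and Serpina1 clusters had fewer and weaker sites than the globin clusters, and other loci of liver genes varied. The albumin cluster (chromosome 5, 90410897 to 90568948; Alb, Afp and Afm) held 4 regions, 2 in replicate 1 and 1 in replicate 2, against an average of 1.56, and its strongest, at 90447810, had a signal of 7.47. The fibrinogen cluster of Fga, Fgb and Fgg held 6 (2 and 3), of which the strongest (18.8) was the promoter of Plrg1, a neighbour named after its value was seen. Around Apoa1, Apoc3, Apoa4 and Apoa5 lay 5 (5 and 3) and around Serpina1a, Serpina1b and Serpina1d 1 (0 and 0). The strongest of the 5, at 12.3 and 11.9, were promoters of the neighbours Zpr1 and Bud13, named after their values were seen. The region nearest to Apoa1 had a signal of 3.73, and the others lay in introns of the neighbour Sik3. Around the hepatic factor gene Hnf4a lay 5 (2 and 3), of which the strongest (12) was the promoter of the neighbour Fitm2. An intragenic promoter of Hnf4a, at 163547112 on chromosome 2, had a signal of 7.14. Around Gata2, a factor of blood progenitors, lay 1 region, and 3 in replicate 1 alone. These counts carry no test, and those for the albumin, apolipoprotein, fibrinogen, Serpina1, Hnf4a and Gata2 regions differed by over 1.5-fold between the combined list and a library's own list.

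**Figure D3:**
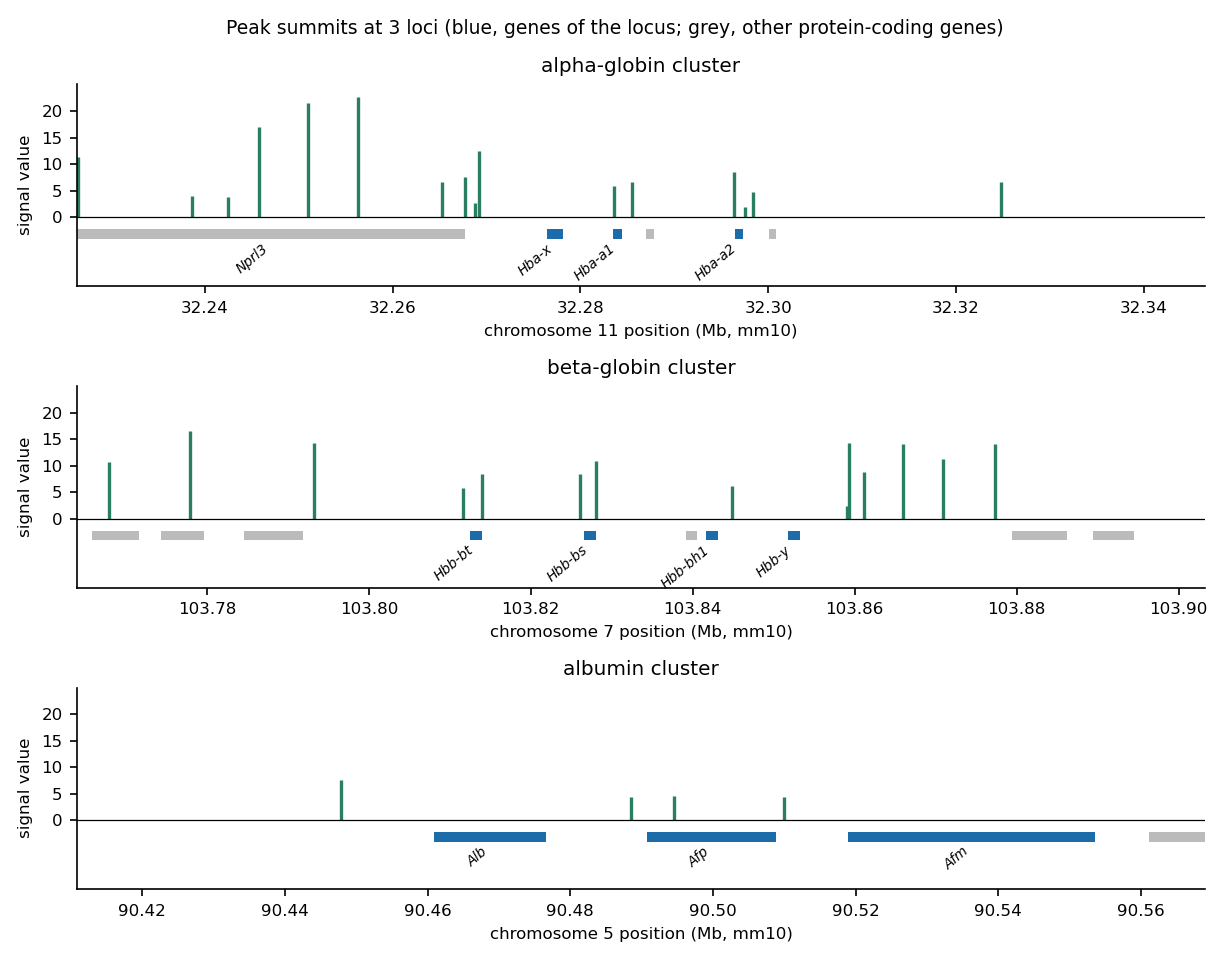
Summits in the α-globin, β-globin and albumin regions, with the authors' signal (vertical axis) against position in the mm10 assembly (horizontal axis), for the conservative list, and genes drawn to scale. The highest summit of the α-globin region reached 22.7, that of the β-globin region 16.4, at the promoter of the neighbouring Olfr68, and that of the albumin region 7.47.

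The strongest promoter peaks lay at genes of varied function, and the strongest distal peaks mostly lay between genes. Arhgap29, a regulator of Rho signalling, had the strongest promoter (chromosome 3, 121967427 to 121968374, signal 33.2; 33.0 in replicate 1 and 29.9 in replicate 2). It was followed by 6720489N17Rik (30.6), Kifap3 (27.8), Gm49359 (27.7), Enox2 (27.4), 2610001J05Rik (27.4), Ccdc181 (27.3), Zfp157 (27.2), Rcn2 (27.0) and Lipa (26.7), the gene of lysosomal acid lipase. The strongest distal peak (chromosome 2, 69355469 to 69355735) had a signal of 57.4 (56.3 and 55.1 in the libraries) and lay 12987 bp from Abcb11. Those next in signal were nearest to Pak3 (56.5), G6pd2 (46.3, at a distance of 1765836 bp), Cdh20 (45.6, at 2140261 bp), Gm5426 (40.7), Frmd4a (39.3), Rtl10 (38.7), Myl12b (37.5), Igf2bp3 (36.0) and Hic2 (34.9). The other 8 lay between 11212 and 58941 bp from the nearest start site. Of the 10, 9 were intergenic and 7 lay in sequence that occurs mostly elsewhere in the assembly as well.

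The windows with the most accessible sites included those of histone genes, the α-globin genes and clusters of tRNA genes. Of 27268 windows of 100 kb, 9709 held a region, 166 held 10 or more, and the mean was 0.984. The densest (chromosome 13, 23500001 to 23600000) held 23 regions, 20 in replicate 1 and 17 in replicate 2, and includes the histone genes Hist1h2af, Hist1h2be and Hist1h2ad. The adjoining window with Btn1a1 and Abt1 held 20 (17 and 12), as did the window of Ctc1, Per1 and Tmem107 on chromosome 11 (17 and 15). The window of BC107364 held 17 (20 and 15), that of Klf1, Dnase2a and Hook2 held 16 (14 and 12), and that of Nprl3, Hba-a2 and Hba-a1 also held 16 (14 and 13). The windows of Fcgr3 (chromosome 1), Dedd2 (7), Hyal2 (9) and Abca7 (10) held 14 each. Annotated tRNA genes lay in 5 of these 10 windows, with 22 in that of Btn1a1 and 20 in that of Fcgr3, and 41 of the windows' 168 regions were within 100 bp of such a gene. The ranks carry no test.

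GATA and NFE2 sequences, which erythroid factors bind, were more frequent under distal summits than 2 kb away. The GATA consensus WGATAA lay within 75 bp of 52.2% of 15647 distal summits and in 14.2% of 14706 background windows 2 kb away, a 3.66-fold difference (3.90-fold in replicate 1 and 3.97-fold in replicate 2). The composite of a partial E-box (CTG alone) and a GATA site, which GATA1 and TAL1 bind together, lay in 8.36% against 0.238%. This was a 34.6-fold difference (39.0-fold and 35.1-fold in the libraries) and 1308 windows. A full E-box was not required. The NFE2 consensus lay in 2.15% against 0.102% (20.5-fold, with 18.6-fold and 25.9-fold in the libraries). AP-1 lay in 7.005% against 2.502% (2.80-fold), and KLF1 in 19.9% against 4.72% (4.21-fold). The KLF1 consensus was not particular to distal sites. It lay in 37.7% of windows of the strongest promoter decile and in 31.3% of the weakest. The insulator factor CTCF had 1.91% against 0.136% (13.7-fold; 14.98-fold and 9.45-fold), NFY 5.21% against 2.67% (1.95-fold) and SP 2.62% against 0.388% (6.71-fold). Against this background the hepatocyte factors HNF4, FOXA and CEBP showed smaller differences. HNF4 lay in 0.320% against 0.190% (1.67-fold), FOXA in 2.70% against 3.28% (0.821-fold) and CEBP in 0.102% against 0.0544% (1.82-fold). Shuffled versions had median ratios of 0.387 for FOXA, 0.766 for CEBP and 0.885 for HNF4, and of 1.91 for KLF1, 1.03 for NFY and 0.5004 for GATA. How far FOXA and CEBP stand below KLF1 and NFY therefore depends on what the ratio is set against. Over 10 alternatives the ratio ranged from 2.32 to 6.42 for GATA, from 20.01 to 58.2 for the composite, from 11.1 to 52.96 for NFE2, from 3.73 to 24.9 for CTCF, from 2.32 to 5.23 for KLF1 and from 2.56 to 7.47 for SP. Direction turned for FOXA against windows matched on GC content (1.802) and for HNF4 (0.617) and CEBP (0.970) among the stronger peaks. The GC content was 52.9% in distal windows and 44.9% in the background windows 2 kb away. Against the GC-matched windows FOXA, HNF4 (1.71) and CEBP (1.94) stood above NFY (1.69). They stayed below KLF1 (2.32), SP, AP-1, GATA, NFE2, CTCF and the composite. HNF1, also a hepatocyte factor, lay in 7 distal windows, YY1 in 6 and REST in 3, and none of them in a background window, where a count of 0 allows a share of up to 0.0204%, above the 0.0192% of distal windows with REST.

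Of the 24 consensus sequences, 0 passed the test fixed before the data were examined, in which the ratio of each was ranked among 50 shuffled versions of itself. In this permutation test (two-sided) 9 reached the smallest p that 50 versions can give, 0.0196, with an adjusted p of 0.0523, and 10 had an unadjusted p under 0.05. At the smallest p the adjusted p depends on how many sequences reach it, and 9 were too few for any to pass. Among the stronger peaks 5 reached it, with a smallest adjusted p of 0.0941 by permutation. The count of 0 therefore cannot decide for any single sequence. The 9 were the composite, NFE2, HNF1, CTCF, YY1, REST, GATA, AP-1 and NFY. The other sequence with an unadjusted p under 0.05 was CEBP, with p = 0.0392 in the same permutation test, and KLF1 had p = 0.0784 in the same permutation test. With up to 1000 shuffled versions, chosen after these values were seen, 8 passed. Among these were HNF1, YY1 and REST, whose ratios rest on 0 background windows, and nothing is read from their p. For the others adjusted p by permutation was 0.00799 for the composite and NFE2, 0.0249 for AP-1, 0.0286 for GATA and 0.042 for NFY, and CTCF had 0.0586. GATA had only 119 distinct shuffled versions, and its unadjusted p by permutation, 0.00833, was the smallest that these allow. Adjusted p of sequences with different numbers of versions are therefore not comparable. Over 10 alternatives the adjusted p ranged from 0.0286 to 0.0941 for GATA, from 0.00799 to 0.0941 for the composite and NFE2, from 0.0249 to 0.0941 for AP-1, from 0.042 to 0.171 for NFY and from 0.0586 to 0.251 for CTCF, all by permutation.

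**Figure D4:**
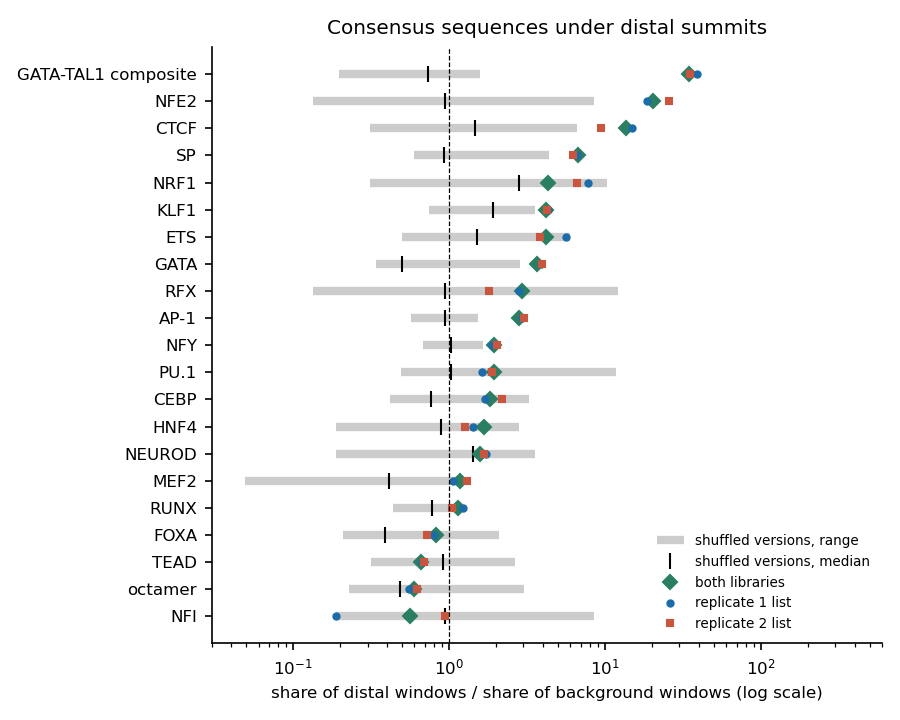
Share of distal windows with a consensus sequence divided by the share of background windows (log scale, horizontal axis), for the conservative list and each library's list, with the range and median of up to 50 shuffled versions in grey and black. The composite stood at 34.6 and GATA at 3.66; 3 of the 24 sequences, HNF1, YY1 and REST, were in 0 background windows and are not drawn.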

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

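In this part, the tests of weak sites behind the longer list and of copies, repeats and GATA sites at the strongest distal peaks were chosen only after the result was seen. The design holds 1 group and so gives no biological contrast to test; the biological explanations tested were GATA sites at the strongest distal peaks and another mix of cells in replicate 1, and none was tested for the absent peaks.

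Peaks passing the authors' score threshold in the ranked list, which the comparisons use only for matched peaks, numbered 58788, and 217 of them were absent from the conservative list, which held the other 58571; this signal lies in data outside the main comparisons. Of the 217, 73 lay outside chromosomes 1 to 19, X and Y, where the conservative list has no peak, and 144 lay in 62 merged regions on these chromosomes. Their median −log10 p was 245 against 57.9 for retained peaks, with the strongest on chromosome 1 from 24611586 to 24616161 (15159, against 14665 for the highest retained). Their median signal was lower, at 4.75 against 5.35 for retained peaks. A shared 31-mer with the mitochondrial genome was found in 10.4% of the 144 (0.0393% of retained peaks). A stretch of chromosome 17 taken as a ribosomal DNA copy shared one with 12.5% (0.00683%). Repeated sequence lay around the summit in 34.0278% (2.4% of 2000 retained peaks sampled). Each is a candidate source for a part of the peaks at most, as far as these reference sequences show. The chromosome 17 stretch is an incomplete copy and shared 0 of 390 31-mers with an annotated 28S ribosomal fragment. That check did not show it to be ribosomal, so its share may miss ribosomal copies or count other sequence. A filter on regions by the authors may have removed them: of the 62 regions, 62 were in the libraries' relaxed lists and 6.45% (4) in any of the 8 lists derived with the further reference file, which hold 0 peaks outside these chromosomes, but those 4 keep it open and the content of that file is not given in the sources used here.

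The 10 strongest distal peaks lay mostly between genes, with signals from 34.9 to 57.4. GATA factors at these sites are argued against, since 0 of the 10 summit windows held the GATA consensus, against 52.2% of all distal windows. Sequence present at several places of the assembly may account for most of them: 7 of the 10 windows had over 50% of their 31-mers elsewhere, against 0 of the 10 strongest promoter windows and 2.4% of retained peaks sampled. Of the 10, 3 shared a 31-mer with mitochondrial DNA and 1 with the chromosome 17 stretch taken as ribosomal DNA. These 4, against 0.0959% of distal regions, are too few to account for the set and too many to set aside. The peaks near Pak3, Frmd4a and Hic2 met neither criterion and stay unexplained. Their windows still had 30.6%, 41.3% and 33.1% of their 31-mers elsewhere, where the median of retained peaks sampled was 0.

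The list of replicate 1 held 4936 regions without a partner in that of replicate 2, while 1133 of replicate 2's lacked one in replicate 1. At the same signal, replicate 1's unshared distal windows held the GATA consensus in 48.7% and its shared ones in 46.9%. The difference was 1.75 points (95% interval −0.536 to 4.03). This argues against a mix of cells with clearly fewer GATA sites at equal signal only. Without matching on signal, shared distal windows held it in 57.6%. A change in the mix of cells that also lowers signal would be hidden by the matching. The interval treats windows of 1 library as independent, so it does not measure variation between pools. Other differences in the mix of cells were not tested. Sites that missed the threshold in replicate 2 may account for most of the 4936, since 86.5% (4271) overlapped replicate 2's relaxed list. After moving regions along the chromosomes 1.74% did. The relaxed list reaches down to a −log10 p of 2.00, and how far under the threshold these sites lay was not checked. Of all regions of replicate 2, 56 lacked a partner in replicate 1's relaxed list. The overlap therefore cannot say why replicate 1's list was the longer one. Whether depth or the larger pool lies behind the longer list stays open, because read counts were not used here and pool and library cannot be separated.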

How the results depend on the processing

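Alternatives chosen after seeing the data were the 1000 shuffled versions, the genes over 1 Mb left out and the regions near tRNA genes left out. No paired analysis was possible because the series has 1 group. The numbers of lists with more promoter peaks (4), more distal peaks (3) and fewer distal peaks (1) stayed within 1.5 times in 10 of 10 alternatives. Lists with fewer promoter peaks numbered 7 in the replicated and 7 in the pooled pseudoreplicated list, against 11. The list of adult hepatocyte genes reversed against lists matched on CpG content (17.1% against 13.9% expected, adjusted p = 0.679 by permutation), as the matching itself lowered the expected share. Of replicate 2's regions 83.5% were overlapped with pseudoreplicated lists, against 94.4%, and of the stronger regions of replicate 1 98.3%, against 79.4%. The promoter share was 26.7% in the replicated, 26.2% in the pooled pseudoreplicated and 56.4% in the stronger list, 46.8% with a window of 2500 bp, and 44.7% to 49.7% with a library left out. The intron share was 38.6%, 39.03%, 22.8% and 27.8% under these, and 26.6% to 29.5% with a library left out, and the intergenic share 31.1%, 31.2%, 19.2% and 23.6%, and 21.8% to 23.5%. A wider promoter window moves summits between classes by construction; for the other lists the cause was not tested. The densest window held 9 regions in the stronger list, against 23, since fewer peaks were counted. Motifs more frequent than their shuffled versions numbered 8 with 1000 versions, against 0, because more versions allow a smaller p. Of 190 values of promoter share 170 kept their side of the threshold, 9 gained a call, 10 lost a call and 1 reversed. Of 190 distal values 187 kept their side and 3 gained a call. Of 240 motif ratios 232 kept their side and 8 gained a call. Values that turned direction without passing in either setting are counted as kept. Hepatoblast genes did so for distal peaks, with a fold of 1.24 in the conservative list and 0.643 and 0.634 in the libraries. Some motif ratios themselves crossed 1, as FOXA did with GC-matched windows. Of 72 counts at loci 38 moved by over 1.5 times, 17 up and 21 down. Without genes over 1 Mb the erythroid, heme and megakaryocyte folds were 4.90, 3.76 and 3.20 (adjusted p 0.00019, 0.000253 and 0.0019 by permutation). Unknown read depth limits what the absence of a peak shows.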

Other observations

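In this part, the test of CCAAT boxes at promoters was chosen only after the result was seen.

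The composition of accessible sites changed with their signal. Among distal windows, the GATA consensus lay in 65.6% of the strongest decile and in 36.6% of the weakest, with 66.2% and 39.1% in replicate 1 and 66.6% and 39.6% in replicate 2. The consensus of the insulator factor CTCF was rarer in the strongest decile (0.128%) than in the weakest (2.24%), with its highest share, 4.03%, in the ninth; the strongest and weakest held 0.0755% and 2.49% in replicate 1 and 0% and 2.56% in replicate 2. Among promoter windows, GATA was in 3.21% of the strongest decile and 13.1% of the weakest. Deciles were compared without a test. Transfer RNA genes, which RNA polymerase III transcribes, were open in large number: 218 of 408 annotated tRNA genes (53.4%; 50.7% in replicate 1 and 43.1% in replicate 2) had a region within 100 bp, against 1.20% after moving the regions along the chromosomes.

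A cluster of tRNA genes may account for part of the densest windows, since 24.4% of their regions (41 of 168) lay within 100 bp of a tRNA gene, against 0.656% of all regions. Such genes lay in 5 of the 10 windows, and the windows of Klf1 and of Nprl3 with the α-globin genes held none. With regions near tRNA genes left out, the histone window on chromosome 13 from 23500001 to 23600000 was still densest, with 17 regions, and 7 of the 10 windows were the same.

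CCAAT boxes, which the factor NFY binds, may mark the strongest promoters. The NFY consensus lay in 32.7% of windows of the strongest promoter decile and in 5.72% of the weakest, a ratio of 5.71 (6.47 in replicate 1 and 5.01 in replicate 2). This pattern was found and tested on the same data.

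Distal windows near liver genes held the GATA consensus less often than those near red cell genes. Near the 3 hepatoblast, hepatic factor and hepatocyte lists 16 of 53 held it (30.2%), and near erythroid and heme genes 74 of 128 (57.8%). The odds ratio was 0.316 (adjusted p = 0.00399 over 4 comparisons, Fisher's exact test, two-sided), which argues against GATA sites being as frequent near both. The test treats windows as independent, although several can lie near 1 gene, and the sets were not matched on signal. Over all distal windows the GATA share was 65.6% in the strongest decile and 36.6% in the weakest. How far signal accounts for the difference was not tested. The GATA composite lay in 2 of 53 against 20 of 128 (adjusted p = 0.0512, exact test) and KLF1 in 14 of 53 against 30 of 128 (0.705). Consensus sequences of HNF4, HNF1, FOXA or CEBP lay in 3 of 53 against 3 of 128, an odds ratio of 2.5 (adjusted p = 0.481, exact test); the bound set beforehand, a test not passing 0.05, was wrong as an exclusion, because 3 windows on each side are too few to decide. A candidate explanation, that these sites belong to hepatoblasts rather than blood cells, may fit the GATA result but was not tested by any value from sorted cells.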
